A study of Homo sapiens with 14 samples.

How the data were processed

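Total RNA from the human melanoma cell lines WM266-4 and A375 was labelled with biotin and measured on 14 Illumina bead arrays, which carry many copies of a short probe per transcript. Per the labels, WM266-4 cells received a control siRNA (3 arrays), FOXD1 siRNA 1 (3 arrays) or FOXD1 siRNA 2 (3 arrays). A375 cells received an empty vector (2 arrays) or a FOXD1 plasmid (3 arrays). The A375 labels speak both of transfected and of transduced cells, so the way of delivery is not settled. Groups and replicate numbers were taken from the sample titles. The labels do not say that replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical.

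The deposited intensity of each probe is on a linear scale and is not normalized, per the file headers; the scanner software is not given in the sources used here. A detection p-value per probe and array stands beside it in the deposited table, per the file headers, and how the authors computed it is not given in the sources used here. The authors also deposited a table of processed log2 values. Set against the intensities, it held log2 of the intensity after quantile normalization within each cell line, with no background subtraction. For the WM266-4 arrays it differed from such a calculation by at most 0.0053.

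The deposited intensity column of A375 empty vector replicate 1 was found to be a copy of that of overexpression replicate 3. Of all probes, 100% had values within 1% of each other in the 2 columns, whereas the highest such share of any other pair of arrays was 7.37%. Across probes, the copied column had a rank correlation of 0.9999 with the authors' log2 values of overexpression replicate 3 and of 0.777 with their log2 values of empty vector replicate 1. Among the dim probes, the detection p-values beside the copied column followed the authors' log2 values of empty vector replicate 1 (rho = 0.983), not the copied intensities (rho = 0.106). The signal of empty vector replicate 1 was therefore taken as the antilog of the authors' log2 values. The same replacement made for empty vector replicate 2 moved its normalized values by a median of 0.00424 and a 99th percentile of 0.0157 on the log2 scale. This replacement was decided after seeing the data, and the copied column as it stands was run as an added alternative.

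Of 48107 probes, 10 with a missing value were left out and 48097 were used. Gene names came from the array platform's annotation of 2016. A single symbol was given for 30107 probes, several for 8 and none for 17982, and the last 2 kinds entered no gene value. Of the named probes, 30068 were matched by gene identifier to the RefSeq genes of assembly GRCh38.p14, and 0 symbols changed. No genome sequence was used here, and no coordinates are given.

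Background was corrected with the normexp model, its background estimated from the detection p-values, with an offset of 16, and the 14 arrays were quantile normalized and put on the log2 scale (limma 3.58.1, R 4.3.3, statmod 1.5.0). A probe was kept if its detection p-value was under 0.05 on at least 2 arrays, which left 32167 probes, 21569 of them named. A gene was represented by its named probe with the highest mean over the arrays. This gave 15544 genes, 4459 of which had several such probes. For 571 of the 1733 genes called with the mean of the siRNAs another probe of the gene was measured, and it was called the opposite way for 3. For overexpression these counts were 363 of 1109 and 0. Called or not, another probe had a change of opposite sign for 125 of the 571 genes and for 69 of the 363. Where a gene lay below background on every array of a group, its fold is given as a lower bound, the bright group's mean against the lowest detected signal of the dim group's arrays.

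A single limma fit (lmFit and eBayes) held the 5 groups without covariates, with 9 residual and 5.09 prior degrees of freedom. The contrasts were each siRNA group against control siRNA, the mean of the siRNA groups against control siRNA, siRNA 1 minus siRNA 2, overexpression against empty vector, and a difference between the lines. The last was overexpression minus vector in A375, minus control minus the mean of the siRNAs in WM266-4. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. Every adjusted p of a gene in the text is from this limma fit unless another is named. Gene lists were tested with camera at a preset correlation of 0.01 between genes, adjusted over the 22 lists, and again with a correlation estimated per list. That estimate came from the fit without the replicate number, so a shift shared by same-numbered arrays can enter it. It was not run with the number as a block. At the preset, 5 lists were called for siRNA 1, 4 for siRNA 2, 5 for their mean, 8 for overexpression, 9 for siRNA 1 minus siRNA 2 and 6 for the difference between the lines. Here siRNA 2 stands for the arrays labelled FOXD1 siRNA 2, in which FOXD1 was not lower. With the estimated correlation, the lists called by camera numbered 0, 1, 0, 0, 2 and 0, against 2, 2, 1, 5, 4 and 3 at an unadjusted p under 0.05. The calls that held were receptor tyrosine kinases and ligands for siRNA 2, and S phase and p53 targets for siRNA 1 minus siRNA 2.

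The samples, contrasts, tests, other settings, gene lists and the rule for named genes were fixed before the data were examined. The lists were melanocytic differentiation, undifferentiated and invasive melanoma, YAP TAZ TEAD targets, TGF-beta targets, MAPK pathway output, receptor tyrosine kinases and ligands, mesenchymal markers, extracellular matrix, S phase and DNA replication, G2 and mitosis, interferon response, NF-kB and cytokines, p53 targets, ATF4 and unfolded protein response, hypoxia and glycolysis, cholesterol synthesis, ribosomal proteins and the FOXD family. A further 4 lists held markers of fibroblasts, keratinocytes, leukocytes and endothelium. Some genes stand in several lists.

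The genes named are FOXD1 and CCN2, which is also called CTGF, and those taken by the following rule. For genes called the same way by both siRNAs, and for overexpression, they are the 6 largest rises and 6 largest falls whose groups do not overlap. For siRNA 1 minus siRNA 2 they are the 3 highest and 3 lowest such genes. For opposite changes they are the 8 genes with the largest smaller-of-both change. Of each list they are up to 3 called members with the largest change for the mean of the siRNAs and for overexpression, or up to 2 members with the smallest p where none was called. The most changed gene of each single siRNA in each direction completes them. Other members are named where a count was 5 or fewer; they were chosen after their values were seen. By chance alone, groups do not overlap, in either direction, for 2.38% of genes with 6 siRNA arrays against 3 control arrays, 20% with 3 against 2 and 10% with 3 against 3.

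Replicate numbers pair the WM266-4 arrays. After group means were removed, the 9 pairs of same-numbered arrays correlated at 0.141 to 0.273 across genes, and no array pair of unlike number was above -0.0464. The titles give the number, and the sources used here do not say what it marks. A fit with the number as a block was among the settings chosen in advance, and its values are printed where they change a WM266-4 call. The other settings were no background correction, an offset of 50, the authors' log2 values, cyclic loess, scaling to the 75th percentile, quantile normalization within each line, other filters and probe rules, trend and robust moderation, array weights, each line alone, stricter thresholds, an estimated correlation, and leaving out each array. The slide as a block was not run, because no slide was given in the sources used here.

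The arrays were of similar brightness. Mean intensity ran from 334.6 to 389.5 and the share of probes detected from 46% to 50.4%. The number of arrays limits the precision. The fit was tested on a single simulated draw per comparison, with 200 of 15544 genes changed and noise independent between genes. More genes than that were called in the data, so the rates below need not hold there. For siRNA 1, it called 79.8% of changes of 1 on the log2 scale and 7.94% of changes of 0.5, with 2.33% of calls false. For the siRNA 2 arrays, it called 82.1% and 24.1% of these, with 7.69% of calls false, and for the mean of the siRNAs 88.6% and 22.1%, with 5.44% false. For overexpression, it called 73.3% of changes of 1 and 0% of changes of 0.5, with 5.93% of calls false. Overlaps of comparisons that share the control arrays were set beside 50 simulations with no effect.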

Results

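Expression was profiled in the melanoma lines WM266-4 and A375, both of which carry a BRAF mutation per the labels, after siRNA against the forkhead transcription factor FOXD1 or its overexpression, as the labels name them. The series title concerns FOXD1 in dedifferentiation and vemurafenib resistance, with CTGF (gene symbol CCN2) as a regulated gene. WM266-4 cells were measured with control siRNA, FOXD1 siRNA 1 and FOXD1 siRNA 2, on 3 arrays each. A375 cells were measured with empty vector on 2 arrays and with FOXD1 overexpression on 3. On 15544 genes, the first principal component held 32.9% of the variance and separated the lines, with WM266-4 arrays at -28.3 to -8.34 and A375 arrays at 28.7 to 44.3. The signal of empty vector replicate 1 is the authors' processed value, because its deposited intensity column repeats that of overexpression replicate 3. Every overexpression result, opposite change and difference between the lines rests on this value. Values with the copied column as deposited are given for some of them, not for each.

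FOXD1 itself was measured first (probe ILMN_1704418). Its log2 signal in WM266-4 was 5.81 ± 0.30 with control siRNA, 4.42 ± 0.14 with siRNA 1 and 5.91 ± 0.10 in the arrays labelled FOXD1 siRNA 2 (SD, n = 3 each). With siRNA 1 it was 2.63-fold lower (SE 0.163 on the log2 scale, limma adjusted p = 8.06e-05), and it was detected on 1 of those 3 arrays. In the arrays labelled FOXD1 siRNA 2 it was not lower: the difference was 0.10 (95% confidence interval -0.25 to 0.451, adjusted p = 0.802). A label field of these arrays names FOXD2 where the others name FOXD1, and FOXD2 differed from control by -0.04 there (interval -0.351 to 0.271, adjusted p = 0.923). Directions drawn from this group therefore rest on the labels, not on a measured loss of FOXD1. The mean of both siRNA groups was -0.65 for FOXD1 (adjusted p = 0.00885); it was -0.47 (adjusted p = 0.0515) without control replicate 3, and -0.24 both without background correction and with the authors' values (adjusted p = 0.0621 and 0.064). In A375, FOXD1 was at 7.31 ± 0.02 with vector (SD, n = 2) and 7.73 ± 0.21 with overexpression (SD, n = 3). The difference of 0.42 did not pass the limma test (interval 0.0301 to 0.814, adjusted p = 0.188), and whether this probe detects the transgene is not known.

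CCN2, a secreted matricellular protein and a classical target of YAP and TAZ, changed in all comparisons with a control (probe ILMN_1699829). It fell from 12.94 ± 0.25 with control siRNA to 9.89 ± 0.12 with siRNA 1 and to 9.65 ± 0.13 in the arrays labelled FOXD1 siRNA 2 (SD, n = 3 each). These falls were 8.27-fold (SE 0.271 on the log2 scale, adjusted p = 7.36e-06) and 9.78-fold (adjusted p = 1.19e-05). In A375 it rose 6.09-fold, from 6.70 ± 0.58 (SD, n = 2) to 9.31 ± 0.63 (SD, n = 3) (limma adjusted p = 0.000394). A further CCN2 probe was 8.52-fold and 9.59-fold lower with the siRNAs and 4.13-fold higher with overexpression. With the copied intensity column of empty vector replicate 1 as deposited, the rise was 1.23 on the log2 scale and was not called (adjusted p = 0.9).

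**Figure D1:**
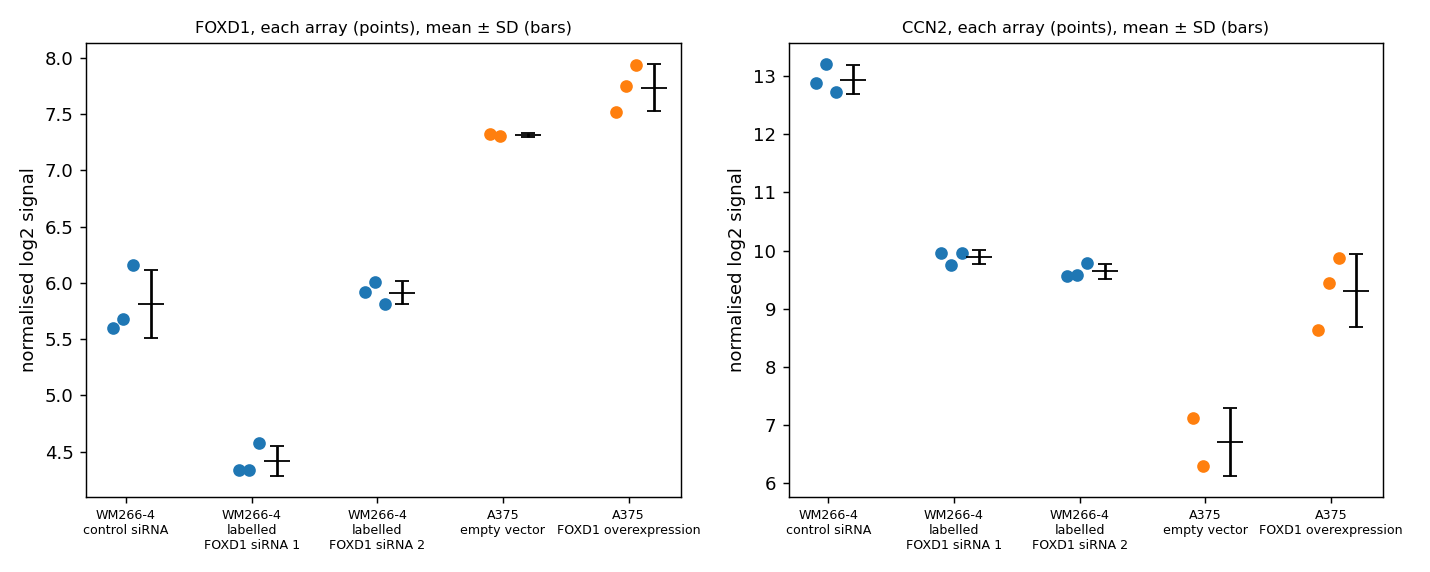
Normalized log2 signal of FOXD1 and CCN2 on each of the 14 arrays, by group; points are arrays and bars show the mean ± SD. FOXD1 was lower with siRNA 1 (mean 4.42) than with control siRNA (5.81) but not in the arrays labelled FOXD1 siRNA 2 (5.91), while CCN2 was lower in both siRNA groups (9.89 and 9.65 against 12.94).

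FOXD1 siRNA 1 was compared with control siRNA to ask which transcripts change in WM266-4 arrays where FOXD1 was lower. The loss of FOXD1 cannot be told apart here from other effects of siRNA 1. The strongest rise was in TXNIP, which binds thioredoxin and limits glucose uptake, at 12.3-fold (SE 0.36 on the log2 scale, limma adjusted p = 1.98e-05). The strongest fall was in DCP2, an mRNA-decapping enzyme, at 8.57-fold (SE 0.159, adjusted p = 6.98e-08). Of 19 measured S phase genes, 15 fell and 1, E2F1, rose (camera adjusted p = 9.26e-14; adjusted p = 0.121 with an estimated correlation). Their members included RRM2, a ribonucleotide reductase subunit (-2.37), SLBP, which binds histone mRNA (-1.49), and the replicative helicase subunits MCM6 (-1.15) and MCM2 (-1.04). Of 22 G2 and mitosis genes 14 fell, among them the mitotic kinase CDK1 (-1.88) (camera adjusted p = 1.06e-10; adjusted p = 0.463 with an estimated correlation).

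In full, 2065 genes were called with siRNA 1, of which 1060 rose and 1005 fell, and 625 changed at least 2-fold. The mean of the S phase list was 8.08 to 8.27 on the siRNA 1 arrays and 9.03 to 9.10 on the control arrays. Adjusted over the list alone, 15 S phase genes fell and 1 rose, and 18 G2 and mitosis genes fell. Of 18 p53 targets, 6 rose, including the cell cycle inhibitor CDKN1A (0.91), and TP53INP1 and CCNG1 fell (camera 0.022; adjusted p = 0.397 with an estimated correlation; 9 and 2 adjusted over the list alone). Of 20 hypoxia and glycolysis genes, 4 fell, the HIF targets ANKRD37, KDM3A, ADM and BNIP3 (camera 0.00136; adjusted p = 0.397 with an estimated correlation; 4 adjusted over the list alone). Of 21 receptor tyrosine kinases and ligands 5 fell, HBEGF, PDGFRB, FGF2, TGFA and EPHA2, by both counts (camera 0.0459; adjusted p = 0.226 with an estimated correlation). That last call was lost with the replicate number as a block (0.0677) and without control replicate 3 (0.083), siRNA 1 replicates 1 and 2 (0.071 and 0.0548), any array labelled siRNA 2 (0.0544 to 0.0606), or overexpression replicates 2 and 3 (0.0566 and 0.0523). The block added the ATF4 list (0.0235) and the cholesterol list (0.0255), the ATF4 list also passed without control replicate 2 (0.0118) or siRNA 1 replicate 3 (0.00369), and the gene count was 1313 without control replicate 2.

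The arrays labelled FOXD1 siRNA 2 were set against the same control arrays. FOXD1 was not lower in them, so they do not put the question of its loss. CCN2 was the gene that fell most, and LRP3, a receptor of the LDL receptor family, rose most, 5.96-fold (SE 0.295 on the log2 scale, limma adjusted p = 0.000145). Receptor and ligand genes fell: of 21 measured, HBEGF (-1.65) and TGFA (-1.57), both ligands of the EGF receptor, the PDGF receptor PDGFRB and the ephrin receptor EPHA2 (-0.91) fell. PDGFRB was not above background on any array of this group and was at least 2.77-fold lower than with control siRNA. Of 18 transcripts that follow ERK activity, EPHA2, DUSP6 (-0.86), which dephosphorylates ERK, IER3 (-0.73) and ETV5 fell, and MYC rose (camera adjusted p = 0.0126; adjusted p = 0.308 with an estimated correlation). Of 19 S phase genes MCM3 rose, 0 fell by limma, and the median was 0.31 (camera adjusted p = 0.00135; adjusted p = 0.402 with an estimated correlation).

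A total of 1021 genes were called in the arrays labelled siRNA 2, with 610 rises and 411 falls, 293 of them at least 2-fold. Adjusted over the list alone, 4 receptor and ligand genes fell (camera adjusted p = 0.000152), which held at an adjusted p = 0.018 with an estimated correlation. In the MAPK list 6 fell and 3 rose adjusted over the list alone. The undifferentiated and invasive list fell in 4 of 21, PDGFRB, WNT5A, NGFR and PLAUR, by both counts (camera 0.0221; adjusted p = 0.308 with an estimated correlation). In the S phase list 2 rose adjusted over the list alone. Without replicate 2 of this group the undifferentiated and S phase calls were lost (0.0914 and 0.0845), and without control replicate 1 the hypoxia list was gained (0.00938). The gene count was 1611 with the replicate number as a block; it was 578 and 553 without control replicates 1 and 2, and 615 and 655 without replicates 1 and 3 of this group.

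The siRNA groups were next compared with each other, a contrast that leaves the control arrays out. DCP2 and RRM2 were lower with siRNA 1, by 7.1-fold and 7.09-fold, as was LEPROTL1, a relative of a leptin receptor regulator, by 5.9-fold. H2AC6, a histone H2A gene (3.88-fold), ACTA2, smooth muscle actin (3.33-fold), and CYSRT1 (3.27-fold) were higher with siRNA 1. The limma adjusted p of these 6 genes ran from 8.86e-08 to 0.00758, and H2AC6 and CYSRT1 were detected on 2 of 3 arrays labelled siRNA 2. Of 19 S phase genes 16 were lower with siRNA 1 and E2F1 was higher; of 18 p53 targets 8 were higher and CCNG1 was lower. Of 22 G2 and mitosis genes 14 were lower (camera adjusted p = 1.95e-18; adjusted p = 0.19 with an estimated correlation).

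In all, 858 genes differed between the siRNA groups, 272 higher and 586 lower with siRNA 1, and 298 at least 2-fold. Adjusted over the list alone, 17 S phase genes were lower and 1 higher (camera adjusted p = 4e-27; adjusted p = 0.0138 with an estimated correlation), and 12 p53 targets were higher and 2 lower (camera 2.45e-06; adjusted p = 0.0426 with an estimated correlation). All 22 G2 and mitosis genes were lower adjusted over the list alone. Camera also called YAP TAZ TEAD targets upward (0.0095), with GADD45A, CCDC80, FJX1 and PTPN14 higher and, adjusted over the list alone, 5 higher and 1 lower. It called mesenchymal markers upward (0.028), with ACTA2 and MMP14 higher and 4 over the list alone, and the undifferentiated list upward (0.028), with 0 members called by limma at either adjustment and 4 at an unadjusted p under 0.05. The FOXD family was lower (0.0407), with FOXD1 the called member by both counts. For these 4 lists, adjusted p = 0.19 with an estimated correlation. Cholesterol synthesis was lower (camera 0.0105; adjusted p = 0.508 with an estimated correlation), with IDI1 called and 2 over the list alone. Hypoxia and glycolysis was lower (camera 0.021; adjusted p = 0.407 with an estimated correlation), with ANKRD37 called by both counts. The YAP, cholesterol, mesenchymal and undifferentiated calls were lost without replicate 2 of the arrays labelled siRNA 2 (0.0548, 0.0588, 0.0925 and 0.127), the undifferentiated call also without siRNA 1 replicate 2 (0.0598), and the hypoxia call without replicate 3 of the arrays labelled siRNA 2 (0.0895). The FOXD call was lost without siRNA 1 replicate 2 or any array labelled siRNA 2 (0.0548 to 0.0771) and with the block in WM266-4 (0.055), while the ATF4 list was gained without siRNA 1 replicate 3 (0.0193). With the replicate block the gene count was 1312 and the matrix and melanocytic lists were added (0.0267 and 0.0377); the count was 476 and 508 without siRNA 1 replicates 1 and 3.

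Genes that moved the same way in both siRNA groups were sought as changes shared by these groups. After CCN2, the largest mean falls were in CTSG, a serine protease (-2.34), CST1, a cystatin protease inhibitor (-2.22), CCN1, a further YAP target related to CCN2 (-2.21), SLC2A3, a glucose transporter (-2.11), and RAMP1, a receptor accessory protein (-1.87). The largest mean rises were in TXNIP (3.08), the channel gene PANX2 (2.75), the lipid kinase gene PIP5K1C (2.66), the autophagy regulator TP53INP2 (2.58), LRP3 (2.56) and TMEM158 (2.38). Some genes were named from the mean of the siRNAs. Among pigment genes TYRP1, a melanosomal enzyme, rose 2.98-fold and PPARGC1A, a mitochondrial coactivator under MITF, rose 2.29-fold, while SLC24A5, a melanosomal exchanger, fell 1.81-fold. WNT5A, a ligand of noncanonical Wnt signalling, fell 2.38-fold. VIM, the intermediate filament vimentin, rose 1.82-fold and ZEB2, a repressor of epithelial genes that is also expressed in melanocytes, fell 1.76-fold. In the arrays labelled siRNA 2 alone, TYRP1 and ZEB2 did not pass (adjusted p = 0.0539 and 0.0747). For the mean, TYRP1 was lost without control replicates 1 or 3 (0.0629 and 0.0763), ZEB2 without control replicate 2 (0.0812), and PPARGC1A without control replicates 1 or 3 (0.0861 and 0.058) and with the authors' values (0.0507). For the 11 genes from CTSG to TMEM158, the SE ran from 0.166 to 0.55 and the limma adjusted p from 1.09e-06 to 0.0137. CST1 was detected on 2 of 3 arrays in each siRNA group, and RAMP1 on 2 and 1.

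Both siRNA groups called 663 genes the same way, 438 up and 225 down, 199 of them at least 2-fold; independent lists would share 41.6 and 26.6. A further 9 genes were called in opposite directions. In 50 simulations with no effect, both siRNA groups were set against the same simulated control arrays. There limma called at most 0 genes the same way, and at an unadjusted p under 0.05 at most 190, against 1717 observed. The simulated noise was independent between genes and between arrays, so a deviation common to many genes of the control arrays is not covered. Across genes, which are not independent replicates, the log2 changes correlated at 0.629 (simulated 0.501), with a covariance of 0.103 (simulated 0.0213, a difference of 0.0813). With 3 controls, which were not split, part of the excess may come from the shared arrays. The shared count was 401 and 376 without control replicates 1 and 2, and 430 without replicate 1 of the arrays labelled siRNA 2. A gene called for the mean of the siRNAs need not change in each group. For the mean, 1733 genes were called, 965 up and 768 down, 319 at least 2-fold; the count was 1030 and 912 without control replicates 1 and 2. Of 56 genes named from the mean besides FOXD1 and CCN2, 35 were called whichever array was left out, and 21 were lost in at least 1 case (adjusted p 0.0506 to 0.235), 17 of them without control replicate 1, 15 without control replicate 2 and 9 without control replicate 3. CTSG was among those lost without control replicate 3 (0.0674), and was also lost with trend and robust moderation (0.0507).

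Among the lists, the mean of the siRNAs lowered 5 of 21 receptor and ligand genes, with HBEGF 3.21-fold, PDGFRB at least 2.73-fold and TGFA 2.51-fold lower and EPHA2 and FGF2 also lower (5 adjusted over the list alone; camera adjusted p = 0.00146; adjusted p = 0.061 with an estimated correlation). Of 18 MAPK output genes 6 fell, including EPHA2 (-0.93), the immediate early gene EGR1 (-0.81) and DUSP6 (-0.78), and MYC rose (7 and 3 adjusted over the list alone; camera 0.0333; adjusted p = 0.476 with an estimated correlation). Of 20 hypoxia genes 4 fell, including ANKRD37 (-1.16), KDM3A (-1.11) and ADM (-0.96), and NDRG1 rose, by both counts (camera 0.00583; adjusted p = 0.476 with an estimated correlation). The S phase list fell in 6 of 19, including RRM2 (-0.96), SLBP (-0.64) and the replication factor CDC45 (-0.59), and 10 fell adjusted over the list alone (camera 0.000761; adjusted p = 0.476 with an estimated correlation). Of 22 G2 and mitosis genes, CDK1 (-0.88) and HMMR (-0.84) fell, and 3 adjusted over the list alone (camera 0.00127; adjusted p = 0.819 with an estimated correlation). The siRNA groups differed from each other in the S phase list (adjusted p = 0.0138 with an estimated correlation), so its mean describes neither group. For G2 and mitosis that difference did not pass camera with an estimated correlation (adjusted p = 0.19), and CDK1 was at -1.88 and 0.11 in the groups. That estimate leaves out the replicate number, with which the G2 and mitosis mean moved. For replicates 1 to 3 it was 7.75, 8.27 and 7.17 with siRNA 1 and 8.81, 9.18 and 8.58 in the arrays labelled siRNA 2. Whether the groups differ in this list is therefore not settled by the estimate. Of the genes, EGR1 was lost without control replicate 1 (0.0625), ADM without control replicate 2 (0.0686), RRM2 without control replicate 3 (0.0795) and CDK1 without control replicates 1 or 2 (0.0677 and 0.11). HMMR was lost without any of 6 arrays (0.0568 to 0.153) and with the mean of a gene's probes (0.0571). The MAPK call was lost without control replicate 2 (0.0571), control replicate 3 (0.0561) or replicate 1 of the arrays labelled siRNA 2 (0.0619), and the hypoxia call without control replicate 2 (0.0713). The ATF4 list passed with the block (0.0318) and without control replicate 2 (0.0129) or siRNA 1 replicate 3 (0.0131).

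FOXD1 overexpression was compared with empty vector in A375 to ask what the added gene changes. The largest rises were in COL8A1, a short-chain collagen (10.9-fold), ST8SIA5, a sialyltransferase (10.3-fold), NTM, a neural adhesion molecule (10.2-fold), HEPACAM, also an adhesion molecule (9.47-fold), ITM2A (9.12-fold) and SORBS2, an adaptor of actin-based adhesions (7.21-fold). The largest falls were in cancer-testis antigen genes, GAGE12E (9.82-fold), GAGE2A (8.2-fold), GAGE12B (7.98-fold), CT55 (6.95-fold) and PASD1 (6.5-fold), and in DHRS2, a dehydrogenase (7.37-fold). The SE of these 12 genes ran from 0.302 to 0.66 on the log2 scale and the limma adjusted p from 0.000168 to 0.0163, and the GAGE values are uncertain because its copies are nearly identical. Of 21 genes of undifferentiated and invasive melanoma 3 rose: SOX9, a neural crest transcription factor (5.2-fold), FST, an activin antagonist (3.61-fold), and the receptor tyrosine kinase AXL (3.32-fold). The camera adjusted p of this list was 0.0134 (adjusted p = 0.19 with an estimated correlation; 0.11 without overexpression replicate 3). Interferon-induced genes rose in 8 of 25, with MX1 (3.69-fold), IRF7 (3.13-fold) and IFIT2 (2.87-fold) in front (camera adjusted p = 5.29e-06; adjusted p = 0.283 with an estimated correlation). HEPACAM was detected on 1 of 2 vector arrays, and DHRS2 and PASD1 on 1 of 3 overexpression arrays.

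With overexpression 1109 genes were called, 570 up and 539 down, 368 at least 2-fold. With each line fitted alone, 207 genes were called. With the copied column as deposited, limma called 0 genes, and 803 at an unadjusted p under 0.05. The count was 142 without empty vector replicate 2 and 581 without overexpression replicate 2. Of 54 genes named from this comparison besides CCN2, 15 were called whichever array was left out: DHRS2, PASD1, HEPACAM, ITM2A, SORBS2, SOX9, FST, COL12A1, COL1A2, BNIP3, RRM2B, IFIT2, MFSD12, MIR100HG and PLSCR4. Without empty vector replicate 2, 39 were lost (adjusted p 0.0542 to 0.289), without empty vector replicate 1, 17 (0.052 to 0.207), and without overexpression replicate 2, 16 (0.0508 to 0.092). NTM was also lost with each line fitted alone (0.064). Overexpression replicate 3 stood apart from the others of its group, with a root mean square log2 difference of 0.482 and 0.47 from them against 0.334 between those.

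Matrix genes rose with overexpression in 7 of 28, with COL12A1, a fibril-associated collagen (3.73-fold), and the proteoglycan BGN (3.36-fold) after COL8A1 (11 up and 1 down adjusted over the list alone; camera adjusted p = 0.000148; adjusted p = 0.19 with an estimated correlation). For interferon genes, 8 rose adjusted over the list alone; the list mean was 7.77, 7.68 and 7.29 on the overexpression arrays against 7.01 and 6.89 with vector. In the undifferentiated list, with SOX9, FST and AXL, 4 rose adjusted over the list alone. YAP TAZ TEAD targets rose in 5 of 20 by both counts: CCN2, AXL, the membrane repair gene MYOF (2.5-fold), NT5E and RBMS3 (camera 0.0134; adjusted p = 0.239 with an estimated correlation). Of 18 p53 targets 4 rose, RRM2B (2.84-fold), TP53INP1 (2.39-fold), the death receptor TNFRSF10B (1.75-fold) and CDKN1A, and 6 adjusted over the list alone (camera 0.00651; adjusted p = 0.19 with an estimated correlation). The S phase list fell in 9 of 19, with MCM2 (2.05-fold), PCNA, the sliding clamp (1.67-fold), and MCM6 (1.66-fold), and 11 adjusted over the list alone (camera 3.54e-07; adjusted p = 0.19 with an estimated correlation). G2 and mitosis fell in 4 of 22, AURKB (2.67-fold), TPX2 (2.43-fold), MKI67 (2.13-fold) and AURKA, and 7 adjusted over the list alone (camera 8.81e-07; adjusted p = 0.379 with an estimated correlation). Hypoxia and glycolysis fell in 6 of 20, with the mitophagy receptor BNIP3 (2.82-fold), hexokinase HK2 (2.33-fold) and enolase ENO2 (2.26-fold), and 8 adjusted over the list alone (camera 0.000706; adjusted p = 0.239 with an estimated correlation). With each line fitted alone, the calls of BGN, IRF7, MYOF, TP53INP1, TNFRSF10B, MCM2, PCNA, MCM6, HK2 and ENO2 were lost (0.0518 to 0.147). PCNA was at -0.29 with the mean of a gene's probes (0.365), and ENO2 was lost with no filter on dim probes (0.0527) and array weights (0.0778). The undifferentiated, YAP and p53 calls were lost without overexpression replicate 3 (0.11, 0.0566 and 0.11). The mesenchymal list was gained without empty vector replicate 2 (0.0401) or overexpression replicate 1 (0.0396), and the receptor list without siRNA 1 replicate 2 (0.047) or with the block in WM266-4 alone (0.04).

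**Figure D2:**
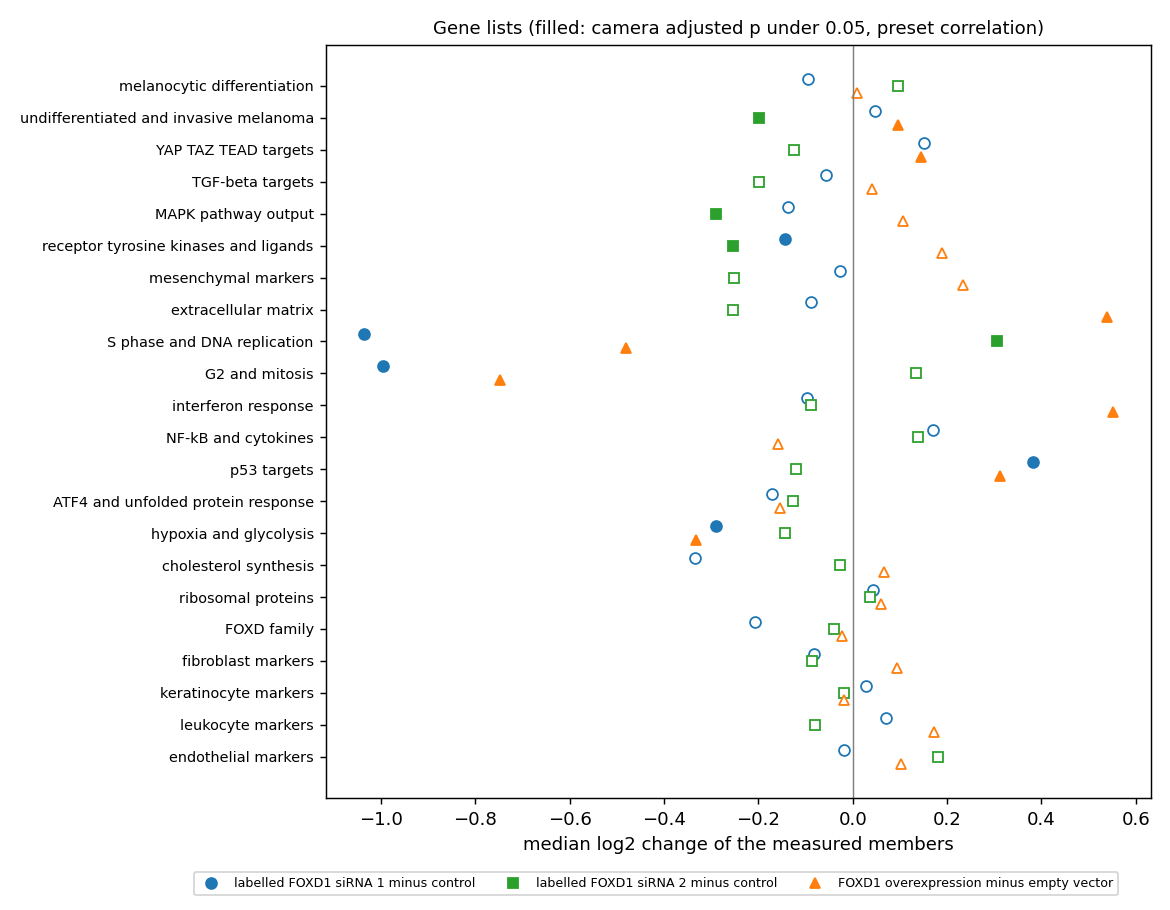
Median log2 change of the measured members of each of the 22 lists for siRNA 1, the arrays labelled FOXD1 siRNA 2 and overexpression, each against its control; filled symbols passed camera at an adjusted p under 0.05 with the preset correlation. S phase medians were -1.04, 0.31 and -0.48 in that order, and the matrix median was 0.54 with overexpression.

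The melanocytic differentiation list was not called in any contrast with a control. With overexpression MLANA, a melanosomal antigen, rose 3.87-fold, S100B rose 2.07-fold and TFAP2A also rose, while IRF4, a pigmentation factor, fell 1.8-fold (camera adjusted p = 0.941, 4 up and 4 down adjusted over the list alone). The mean of this list was 8.65 on overexpression replicate 3 and 9.43 and 9.39 on the others of the group, against 9.23 and 9.29 with vector. For the mean of the siRNAs, 2 of 27 rose and 1 fell, by both counts (camera 0.862). The undifferentiated list had 2 falls of 21 for that mean, PDGFRB and WNT5A, and 6 falls and 1 rise adjusted over the list alone (camera 0.255). YAP TAZ TEAD targets did not pass for it (camera 0.857): CCN2 and CCN1 fell, FJX1 (1.7-fold) and GADD45A rose, and 6 fell and 4 rose adjusted over the list alone. For mesenchymal markers VIM and ITGA5 (1.52-fold) rose and ZEB2 fell of 16, with 3 up and 1 down adjusted over the list alone (camera 0.716); with overexpression ACTA2 (3.73-fold) and SPARC (1.91-fold) rose, and 6 up and 1 down over the list alone (camera 0.103). Of 28 matrix genes, THBS2 (1.9-fold) and VCAN (1.55-fold) rose and the laminin LAMA4 fell (1.88-fold) for the mean of the siRNAs, with 2 up and 2 down adjusted over the list alone (camera 0.527). Receptor genes AXL, EPHA2 (1.54-fold) and FGF2 rose and MET fell (1.7-fold) with overexpression, with 5 up and 2 down adjusted over the list alone (camera 0.0552). In the MAPK list EPHA2 rose and IER3 fell (1.65-fold) with overexpression, with 3 and 1 adjusted over the list alone (camera 0.616). With each line fitted alone, the overexpression calls of MLANA (0.119), S100B (0.0581), IRF4 (0.0724) and SPARC (0.101) were lost. That and other settings chosen in advance lost EPHA2 (0.0631 to 0.126), MET (0.0544 to 0.102) and IER3 (0.0595 to 0.175) with overexpression and ITGA5 with the siRNAs (0.0501 to 0.0584), and LAMA4 was lost with no filter on dim probes (0.0534) and with trend and robust moderation (0.0639). Without empty vector replicate 2, MLANA (0.218), S100B, IRF4, ACTA2, SPARC, AXL, EPHA2, MET and IER3 were lost (0.0784 to 0.266). With the siRNAs, leaving out any of at least 7 arrays lost ITGA5 (0.057 to 0.235), LAMA4 (0.0672 to 0.142) and VCAN (0.0529 to 0.117).

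The TGF-beta, NF-kB, ATF4 and cholesterol lists did not pass camera for the mean of the siRNAs or for overexpression, and the interferon and p53 lists did not pass for the mean of the siRNAs. Of 18 TGF-beta targets, BMPR2 (-0.55) and TGIF1 (-0.54) fell with the siRNAs by both counts (camera adjusted p = 0.176). BMPR2 was lost without any of 7 WM266-4 arrays (0.0566 to 0.125), and TGIF1 without control replicates 1 or 2 (0.104 and 0.0751) and with the mean of a gene's probes, at -0.20 (0.268). For these targets, with overexpression limma called 0 and 1 at an unadjusted p under 0.05, and BHLHE40 was at -0.70 and ID3 at -0.66, with adjusted p of 0.116 and 0.264 (camera 0.941). Among 16 NF-kB and cytokine genes, the adhesion molecule ICAM1 (-1.31) and the cytokine LIF (-0.86) fell, and TNFAIP3 (0.83) and NFKBIA rose with the siRNAs, with 4 up and 4 down adjusted over the list alone (camera 0.716); the chemokine CXCL8 rose with overexpression (1.13), with 1 up and 1 down over the list alone (camera 0.941). Of 25 interferon genes limma called 0 with the siRNAs by both counts and 4 at an unadjusted p under 0.05, with XAF1 at -0.42 (adjusted p = 0.0899) and IFI44 at 0.41 (adjusted p = 0.108; 0.0375 with the block and 0.0292 without control replicate 2; list camera 0.585), and control replicate 2 had a list mean of 7.69 against 6.87 and 6.78. The p53 targets DDB2 (0.56), CDKN1A (0.42) and AEN (0.39) rose with the siRNAs, with 4 up and 1 down over the list alone (camera 0.606). With siRNA 1 and in the arrays labelled siRNA 2, CDKN1A was at 0.91 and -0.07, AEN at 0.76 and 0.02 and DDB2 at 0.66 and 0.45. The list differed between these groups (adjusted p = 0.0426 with an estimated correlation), so its mean describes neither. The CDKN1A call was lost with cyclic loess (0.0678), 75th percentile scaling (0.0916), quantile normalization within each line (0.0578) and the mean of a gene's probes (0.235). Leaving out single arrays lost CDKN1A (0.0591 to 0.145), AEN (0.0509 to 0.135), DDB2 (0.0835 and 0.109), LIF (0.0506 to 0.155), TNFAIP3 (0.0565 to 0.159) and DDIT3 (0.0511) with the siRNAs, control replicate 1 among the arrays in each case. Of 21 ATF4 genes, MTHFD2 (2-fold), DDIT3 (1.83-fold) and DNAJB9 fell and CEBPB (1.61-fold) rose with the siRNAs by both counts (camera 0.0975); SLC3A2 fell (-0.98) and DNAJB9 rose (0.83) with overexpression by both counts (camera 0.878). In cholesterol synthesis LSS rose (1.40) and IDI1 fell (-0.72) of 15 with the siRNAs by both counts (camera 0.527), and SC5D rose (0.93) with overexpression by both counts (camera 0.941). LSS was lost with the mean of a gene's probes (0.0854). The overexpression calls of CXCL8, SLC3A2, DNAJB9 and SC5D were lost with each line fitted alone (0.0518 to 0.125) and without empty vector replicate 2 (0.0667 to 0.206), and SLC3A2 also with array weights (0.0559).

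Limma called 0 of 19 ribosomal protein genes by either count, and 1 and 2 at an unadjusted p under 0.05 for the siRNAs and overexpression, with RPL13 at 0.48 and RPL14 at 0.21 for the siRNAs (adjusted p = 0.0884 and 0.263; camera 0.585) and RPL7 at 0.53 and RPL30 at 0.43 for overexpression (adjusted p = 0.0668 and 0.0967; camera 0.557). RPL13 passed without control replicate 3 (0.0226), and RPL7 without control replicate 2 (0.049) or overexpression replicate 3 (0.0454). Without background correction, with the authors' values and with trend and robust moderation, RPL13 (0.0385 to 0.0469), RPL7 (0.0183 to 0.026) and RPL30 (0.0164 to 0.0255) passed; RPL7 and RPL30 also passed with an offset of 50 (0.0267 and 0.0348) and RPL14 with the mean of a gene's probes (0.0378). In the FOXD family FOXD4 rose 1.53-fold and FOXD1 fell of 5 with the siRNAs by both counts (camera 0.606); with overexpression limma called 0, and FOXD1 alone at an unadjusted p under 0.05, with FOXD3 at -0.19 (camera 0.941). FOXD4 was lost without background correction (0.0601), with the authors' values (0.0696), with the mean of a gene's probes (0.0906) and without control replicates 1 or 2 (0.0588 and 0.0838). Of 9 fibroblast markers PDGFRB fell with the siRNAs by both counts (camera 0.35), and COL1A2 rose 3.01-fold with overexpression, with 1 up and 1 down adjusted over the list alone (camera 0.608). Of 3 keratinocyte markers limma called 0 in either comparison, and 0 at an unadjusted p under 0.05, with DSP at 0.09 for the siRNAs (camera 0.862 and 0.878). DSP was not above background on the vector arrays. KRT14 was not above background on the siRNA arrays and was at -0.33 with overexpression (adjusted p = 0.27). Of 6 leukocyte markers limma called 0 with the siRNAs by both counts and 1 at an unadjusted p under 0.05, with LYZ at 0.28 (camera 0.901), and CD14 rose 3.16-fold with overexpression by both counts (camera 0.185), a call lost without empty vector replicates 1 or 2 (0.0609 and 0.0812) and with each line fitted alone (0.0949). CD14 was at -0.61 with the siRNAs (adjusted p = 0.164), which passed with the block (0.019), with each line fitted alone (0.0338) and without overexpression replicate 3 (0.0195). Of 7 endothelial markers limma called 0 by both counts in either comparison (camera 0.716 and 0.941), and 1 and 0 at an unadjusted p under 0.05, with EGFL7 at -0.32 for the siRNAs; TEK was not above background on the control arrays of either line but passed for the siRNAs with the authors' values (0.047), and PECAM1 was not above background on the overexpression arrays but passed without empty vector replicate 1 (0.0479). For the mean of the siRNAs, median and mean differed in sign for the melanocytic list (-0.02 and 0.03), YAP targets (0.09 and -0.22, test down) and NF-kB genes (0.25 and -0.05, test up). For overexpression they differed for the melanocytic (0.01 and -0.10), NF-kB (-0.16 and 0.07, test down), FOXD (-0.02 and 0.04) and endothelial (0.10 and -0.03) lists and for TGF-beta targets.

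Genes called in opposite directions for the mean of the siRNAs and for overexpression were sought. These comparisons are named by their labels: FOXD1 was not lower in the arrays labelled siRNA 2 (0.10, adjusted p = 0.802), and its rise with overexpression did not pass (0.42, adjusted p = 0.188). CCN2 and CST1 fell with the siRNAs and rose with overexpression, CST1 by 4.67-fold and 4.63-fold. MIR100HG, a long noncoding RNA that hosts microRNAs (2.3-fold and 4.03-fold), CREBRF, a regulator of CREB3 proteins (2.24-fold and 2.33-fold), and PLSCR4, a phospholipid scramblase (2.14-fold and 3.64-fold), did likewise. MFSD12, a lysosomal transporter that affects pigmentation, rose 3.35-fold with the siRNAs and fell 3.19-fold with overexpression. GOLGA7B (3.12-fold and 2.25-fold) and PRR7 (3.19-fold and 2.04-fold) also rose and then fell. For these genes the limma adjusted p ran from 2.58e-06 to 0.00381 with the siRNAs and from 0.000168 to 0.0428 with overexpression. The single siRNA 1 value of MIR100HG did not pass (-0.81, adjusted p = 0.0521).

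In all 137 genes were called in opposite directions, 60 up and 77 down with the siRNAs, against 33.5 and 28.2 for independent lists, and 10 changed at least 2-fold in both. In the same direction 45 rose and 43 fell, against 35.4 and 26.6. These comparisons share no array, but they share the fit, its spread per gene and the normalization. Their calls are therefore not independent, and part of either excess may come from this. Of genes called the same way by both siRNA groups, 66 moved oppositely with overexpression and 26 the same way. Across all genes, which are not independent, the log2 changes correlated at -0.0694. Opposite changes numbered 20 with each line fitted alone. The count of opposite genes was 0 with the copied column as deposited, where limma called no gene with overexpression (803 at an unadjusted p under 0.05), 13 without empty vector replicate 2, 69 without overexpression replicate 2, 73 and 74 without control replicates 1 and 2, and 243 with the replicate block. Calls with overexpression were lost without empty vector replicate 2 for CST1 (0.222), GOLGA7B (0.174), CREBRF (0.0542) and PRR7 (0.289). CST1 was also lost without empty vector replicate 1 or overexpression replicates 2 or 3 (0.0603 to 0.0912), and PRR7 without any other A375 array (0.0671 to 0.102) or without siRNA 1 replicate 2 or replicates 1 or 2 of the arrays labelled siRNA 2 (0.0505 to 0.056). With all arrays, CST1 was lost with trend and robust moderation (0.0515) and array weights (0.0524), and GOLGA7B with the mean of a gene's probes (0.0514) and each line fitted alone (0.0703). PRR7 was lost with no filter on dim probes (0.0556), array weights (0.0927) and each line fitted alone (0.062).

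**Figure D3:**
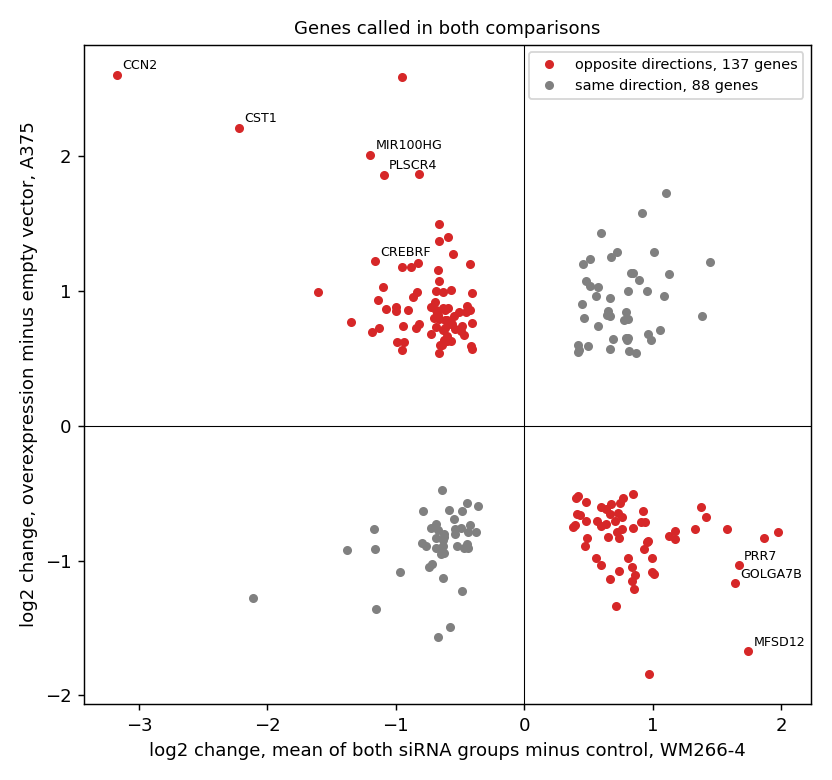
Log2 change with the mean of the siRNAs against log2 change with overexpression for genes called in both comparisons; red points moved oppositely (137) and grey points the same way (88). CCN2 lies at -3.17 and 2.61.

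The changes were also compared between the lines, taking control minus the mean of the siRNAs in WM266-4 and overexpression minus vector in A375. By label both run toward more FOXD1, but it was not lower in the arrays labelled siRNA 2 and its difference in A375 did not pass. A lower or higher value in A375 here is that of the change, not of the signal. Of cell cycle genes, 11 of 19 S phase genes and 6 of 22 G2 and mitosis genes had a lower value in A375. The S phase median was -1.04 with siRNA 1, 0.31 in the arrays labelled siRNA 2 and -0.48 with overexpression, each against its control. The mean of the siRNAs used here describes neither siRNA group for this list, and siRNA 1 carried its fall. All list calls in this comparison were lost with an estimated correlation (adjusted p = 0.305 for S phase and 0.53 for G2 and mitosis). MCM2 fell with overexpression (-1.03) and with siRNA 1 (-1.04) but was at 0.26 in the arrays labelled siRNA 2. Its mean of the siRNAs was not called (-0.39, limma adjusted p = 0.19), and its difference between the lines passed (limma adjusted p = 0.00866). Of 20 hypoxia genes, 7 had a lower value in A375, among them BNIP3 (adjusted p = 0.00104). Among matrix genes COL8A1, COL12A1, COL1A2, VCAN and THBS2 had a higher value in A375 and LUM a lower one, and of 25 interferon genes MX1, IFIT2, MX2 and BST2 had a higher one. RRM2B, CDKN1A and TNFRSF10B were the p53 targets with a higher value. With siRNA 1 and in the arrays labelled siRNA 2, RRM2B was at 0.64 and -0.09, CDKN1A at 0.91 and -0.07 and TNFRSF10B at 0.30 and -0.43. The p53 list differed between these groups, so the mean used here describes neither. The difference in CCN2 did not pass (-0.56, interval -1.39 to 0.259, adjusted p = 0.425); with its further probe it was -1.13 (interval -1.93 to -0.337), with an adjusted p of 0.0849 over all probes.

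This difference between changes passed for 1289 genes, 690 higher and 599 lower in A375, 791 at least 2-fold; the count was 187 with the copied column as deposited, 475 without empty vector replicate 2 and 756 without control replicate 2. Camera adjusted p was 7.34e-10 for both cell cycle lists (adjusted p = 0.305 and 0.53 with an estimated correlation; 12 and 17 lower adjusted over the list alone), and 1.1e-05 for hypoxia (0.305 with an estimated correlation; 8 lower over the list alone). It was 0.0175 for matrix genes (0.53 with an estimated correlation; 7 up and 1 down over the list alone), 0.00387 for interferon genes (0.576 with an estimated correlation; 4 up over the list alone) and 0.00824 for p53 targets (0.318 with an estimated correlation; 6 up over the list alone). The matrix and p53 calls were lost without overexpression replicate 3 (0.0833 and 0.119) and the interferon call without control replicate 3 (0.0775), while the ATF4 list was gained without control replicate 2 (0.0449).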

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

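The test of overexpression replicate 3 as a vector array, the test of the difference between the lines and the counts of splits were chosen before the result was seen, and the other tests of explanations here were chosen after it. The difference between the lines is that of changes, overexpression minus vector in A375 against control minus the mean of the siRNAs in WM266-4, not of levels. Its test passed for 1289 genes. Camera adjusted p for that difference was 7.34e-10 for S phase genes and 7.34e-10 for G2 and mitosis genes, whose change was lower in A375, and 1.1e-05 for hypoxia genes, also lower. It was 0.0175 for extracellular matrix genes, 0.00387 for interferon genes and 0.00824 for p53 targets, all with a higher change in A375. None of these 6 list calls held with an estimated correlation: adjusted p = 0.305 for S phase, 0.53 for G2 and mitosis, 0.305 for hypoxia, 0.53 for matrix, 0.576 for interferon and 0.318 for p53 (3 at an unadjusted p under 0.05 with that correlation). The S phase and p53 lists differed between the siRNA groups, so the mean of the siRNAs describes neither. S phase medians were -1.04 with siRNA 1, 0.31 in the arrays labelled siRNA 2 and -0.48 with overexpression. For p53 targets they were 0.38, -0.12 and 0.31 in that order. ACTA2, which encodes smooth muscle actin, rose with siRNA 1 and with overexpression. It was at 0.02 in the arrays labelled siRNA 2, and the mean of the siRNAs was not called (0.89, limma adjusted p = 0.0701). Its difference between the lines, which takes that mean, passed at a limma adjusted p of 0.00357. The lines differ in the kind of manipulation as well as in origin, so the design confounds the line with siRNA against overexpression.

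The arrays labelled FOXD1 siRNA 2 shared changes with siRNA 1, CCN2 among them, although their FOXD1 signal was not lower. Control arrays under a wrong label are argued against by the 1021 genes that limma called between this group and the controls. That count was known when the test was chosen. In each of the other splits of these 6 arrays limma called 0 (at most 1076 at an unadjusted p under 0.05, against 3118). Such splits mix the groups, which widens the spread, so a low count there adds little. The 10 splits are also too few for a share under 0.05. That the shared control arrays are what differs remains open; among genes called the same way by both siRNAs and called in A375, which shares no array with them, 66 moved oppositely and 26 the same way, or 71.7% oppositely (exact binomial interval 61.4% to 80.6%, over genes that are not independent). Over all 663 genes called the same way by both siRNAs, called in A375 or not, the mean opposite change was 0.131. It was at most 0.0389 in the other of the 10 splits of the A375 arrays, too few for a share under 0.05. A fall of FOXD1 protein, an earlier fall of its transcript, and effects common to siRNAs were not tested here.

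S phase genes were lower with siRNA 1 and with overexpression and not in the arrays labelled siRNA 2. The siRNA 1 call was lost with an estimated correlation (adjusted p = 0.121), and the difference between the siRNA groups held (adjusted p = 0.0138). A single array as the source of the fall with siRNA 1 is argued against, since the highest siRNA 1 array lay -0.759 from the lowest control array in the mean of the list. The list might follow FOXD1 in both lines, which would give a rise with overexpression, but its median there was -0.48. This does not decide the matter, because the overexpression call was lost with an estimated correlation (adjusted p = 0.19) and the FOXD1 probe did not rise past the test. An effect of the siRNA 1 sequence on other transcripts stays open and untested, as does a different role of FOXD1 in each line.

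Overexpression replicate 3 stood apart from replicates 1 and 2. A vector array under a wrong label is argued against: over 1041 genes called without replicate 3, its median share of their change was 0.731, and 93.3% moved the same way. A dim array is argued against by its 47.3% of probes detected, within the 46% to 50.4% of the others. A separate culture or gene delivery stays open, and no label gives one.

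For siRNA 1 against control, 1 of 10 splits of the arrays, the real one, gave 2065 genes, and the highest other gave 0 by limma (996 at an unadjusted p under 0.05). For the arrays labelled siRNA 2 against control, 1 of 10 gave 1021, and the highest other 0 (1076 at an unadjusted p under 0.05). For siRNA 1 against siRNA 2, 1 of 10 gave 858, and the highest other 0 (1003 at an unadjusted p under 0.05). These splits are too few for a share under 0.05. For both siRNA groups against control, 1 of 84 splits gave as many genes as the real 1255, which makes chance unlikely without excluding it. That fit took the 6 siRNA arrays as 1 group, unlike the fit behind the 1733 genes for the mean of the siRNAs. The highest other, 966, set the siRNA 1 arrays against the rest, and the highest that kept no group together gave 33. Of the 27 splits that set 1 array of each number apart, the highest besides the real one was the same 966. These splits cannot tell an effect of the siRNAs from another difference between the control arrays and the rest. For genes called the same way by both siRNAs, 1 of 100 splits drawn gave as many as the real 663, and the highest other drawn gave 503 and kept the control arrays together. With the siRNA 1 and control arrays exchanged the count was 535, and with the siRNA 2 and control arrays exchanged 114. The numbers pair these arrays, and the 15 drawn with 1 array of each number in each group, where the highest other was 495, are too few for a share under 0.05.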

How the results depend on the processing

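The copied column of empty vector replicate 1 as deposited, the block in WM266-4 alone and, for the lists, leaving out arrays were chosen after seeing the data, and the other settings before. In what follows siRNA 2 stands for the arrays labelled FOXD1 siRNA 2, in which FOXD1 was not lower. With the copied column, limma called 0 genes with overexpression (803 at an unadjusted p under 0.05), 0 opposite genes and 187 genes for the difference between the lines (of changes, not levels), 4 lists with overexpression and 3 for the difference, and CCN2 rose by 1.23, not called. The cause is the column itself, since a vector array then equals an overexpression array.

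At an adjusted p under 0.01, genes called numbered 1074 for siRNA 1, 422 for siRNA 2, 798 for their mean, 295 the same way by both, 252 for overexpression, 376 for siRNA 1 minus siRNA 2, 16 opposite and 369 for the difference between the lines. At 2-fold or more they numbered 625, 293, 319, 199, 368, 298, 10 and 791 in that order. With each line fitted alone, overexpression called 207 and opposite changes 20, with fewer arrays to estimate the spread. Opposite changes numbered 258 without background correction, 245 with an offset of 50, 263 with the authors' values and 208 with trend and robust moderation; the cause was not tested. The mean siRNA value of FOXD1 was -0.243 without background correction and -0.24 with the authors' values, neither called; the cause was not tested, and FOXD1 lies near background there. Camera with an estimated correlation called 0 lists for siRNA 1, 1 for siRNA 2, 0 for their mean, 0 for overexpression, 2 for siRNA 1 minus siRNA 2 and 0 for the difference between the lines.

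With the replicate block, the numbers called were 1611 for siRNA 2, 1312 for siRNA 1 minus siRNA 2 and 243 opposite (175 with the block in WM266-4 alone), and 5 lists with overexpression. In WM266-4 it changed no other call of a named gene or list than those printed beside their results. With the block in WM266-4 alone, 1 call of a named gene was gained and 0 were lost, so IFI44 and CD14 did not both pass there. In A375 the numbers do not pair the arrays (correlations -0.0295 and 0.0378); there the block took the undifferentiated list to 0.154, the YAP list to 0.075 and the p53 list to 0.16, and the p53 difference between the lines to 0.146. With overexpression it also lost IER3 (0.0796) and ENO2 (0.0748) and gained RPL7 (0.0332) and FOXD3 (0.049). The slide as a block was not run.

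Leaving out each array gave 1313 to 2326 genes for siRNA 1, 553 to 1265 for siRNA 2, 912 to 1991 for their mean, 376 to 795 the same way by both, 142 to 1084 for overexpression, 476 to 1008 for siRNA 1 minus siRNA 2, 13 to 135 opposite and 475 to 1329 for the difference between the lines. Lists called ran from 4 to 6, 2 to 5, 4 to 6, 5 to 9, 4 to 10 and 4 to 7 for siRNA 1, siRNA 2, their mean, overexpression, siRNA 1 minus siRNA 2 and the difference between the lines. FOXD1 ran from -1.5 to -1.22, -0.00429 to 0.274, -0.751 to -0.473 and 0.321 to 0.531, and CCN2 from -3.16 to -2.91, -3.4 to -3.15, -3.28 to -3.03 and 2.19 to 3.02 for the first 4 of these. With a lone vector array, that array is assumed to vary like the other groups.

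Of 2067 values of named genes under settings chosen before, 1938 kept their side of the threshold, 111 lost the call and 18 gained it. With an array left out, 1751 of 1932 kept it, 175 lost the call and 6 gained it. Under added settings these were 213, 62 and 1 of 276. Among 1958 list results under settings chosen before, 1878 kept their side, 60 lost the call and 20 gained it. With an array left out these were 1808, 30 and 10 of 1848. Direction was compared only where a result was called as reported or under the other setting, and there 0 reversed. Where neither was called, the direction was not compared. With 75th percentile scaling, the median log2 change of all genes for siRNA 1 was -0.0503, against 0.00513 as reported, the farthest from it among the scalings and contrasts. Genes near background, as where a probe was detected on part of a group's arrays, have values limited by the signal over background.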

Other observations

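The family tests here were chosen after the values were seen. Among 19 gene families tested in both directions for 4 contrasts (152 tests, Fisher's exact test over genes that are not independent), 3 passed. GAGE genes, cancer-testis antigens, fell with overexpression in 11 of 12 (adjusted p = 1.39e-13, median -2.59), and GAGE10 was at -0.47 (limma adjusted p = 0.29). All 12 had lower values in every setting, but limma called 0 with the copied column of empty vector replicate 1 or without empty vector replicate 2 (11 at an unadjusted p under 0.05 each), 4 without empty vector replicate 1, 4 without overexpression replicate 2 and 2 at an adjusted p under 0.01. These settings leave out the one that tested every probe, which was not looked at for this family. The copies are nearly identical, so the probes do not count separate genes with certainty. Genes whose symbol begins with COL, genes or pseudogenes of extracellular matrix collagens except COLEC11, COLGALT1 and COLQ, rose with overexpression in 7 of 39 (adjusted p = 0.0241) and fell in 2. Those that rose had COL16A1 at 1.43, COL22A1 at 1.34, COL15A1 at 1.24 and COL14A1 at 1.01 besides COL8A1, COL12A1 and COL1A2; COL7A1 fell by 0.92 on the log2 scale and COLGALT1, an enzyme that modifies collagen, by 0.62. Protocadherin genes, genes or pseudogenes of adhesion molecules, rose with siRNA 1 in 11 of 46 (adjusted p = 0.0156). Among them were PCDHB5 (1.39), PCDHB12 (1.23) and the pseudogene PCDHB17P (1.13). In the arrays labelled FOXD1 siRNA 2, in which FOXD1 was not lower, 2 of 46 rose (adjusted p = 1), and for the mean of the siRNAs 8 of 46 did (adjusted p = 0.207). The difference between the siRNAs was not tested for this family.

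In the control groups, which received no FOXD1 reagent, the levels were unlike. CCN2 was at 12.94 with control siRNA in WM266-4 and 6.70 with vector in A375, and FOXD1 was at 5.81 and 7.31. No untreated cells were measured, so the line cannot be told apart from control siRNA against empty vector. These differences between the control groups were not tested.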
